A study of Drosophila melanogaster with 3 samples.

How the data were processed

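Chromatin immunoprecipitation followed by sequencing was done on whole Drosophila melanogaster prepupae of mixed sex that carried the product of the gene CG7368 fused to green fluorescent protein, and an antibody against that protein was used for the precipitation. Per the labels, chromatin was sheared by sonication to fragments of 200 to 800 bp, and the 3 libraries are biological replicates of a single group. The labels name a possible control experiment, which is not analysed here.

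The values used are peak lists that the authors deposited, in dm6 and dm3 coordinates. Each replicate has a list of regions that served as input to the irreproducible discovery rate (IDR) procedure. IDR judges from the agreement of ranks between replicates how far down a list regions are kept. A pooled list was made from the alignments of all 3 replicates, and an optimal list holds the regions retained by IDR, per the labels and the accompanying description. The labels describe the pooled list as peaks and background. The signal of each region is the value the authors deposited from their peak caller, and its formula is not given in the sources used here. The −log10 q-value of each region was also deposited by the authors and was used only to describe the lists. The peak caller, the aligner and the number of reads are not given in the sources used here, so the depth behind each region is unknown, and signals were used only to rank and describe regions within 1 list, and ranks, not signals, were compared between replicates. Regions are called optimal peaks where the authors' optimal list holds them, and not retained where a region of the pooled list overlaps none of these. Alignments and signal tracks are not used here.

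Lists were read as deposited, with starts converted to 1-based positions. Positions of dm6 lists were compared with a reference of the same assembly, and all dm6 regions lie inside its chromosomes. Genes came from Ensembl release 115. Of 17834 genes with the same name in a second annotation of that assembly, 17831 had the same start and end. The 5896 transposable elements annotated as genes were left out, which left 18358 genes, 13986 of them protein-coding. No position was converted between builds, and dm3 lists served only for alternatives that need no annotation.

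Agreement of replicates was the share of the 5246 regions with the highest signal in 1 replicate that overlapped by at least 1 bp the 5246 highest of another, averaged over both directions, where 5246 is the number of optimal peaks. It was set against 100 shuffles of positions on the same chromosomes. A summit within 500 bp of an annotated transcription start site (TSS) was called a promoter summit. Promoter and X chromosome shares were compared between optimal peaks and regions not retained by Fisher's exact test, two-sided, with 95% intervals of the odds ratio from its standard error and Wilson intervals for shares. Regions are not independent animals, so the same shares are also given for the 5246 highest regions of each replicate as mean ± SD. The difference in median signal was tested by permutation of 100000 resamples, two-sided, whose smallest p is 1e-05, with an interval from 2000 bootstrap draws. For 3 replicates alone a sign-flip test cannot go below 0.25.

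For 18 gene lists, members with an optimal promoter summit were compared with all other protein-coding genes that had at least 1 pooled region at a promoter, by Fisher's exact test with Benjamini-Hochberg adjustment over the lists. List members were matched by symbol, and 10 list entries that named no gene of the annotation as written were left out, of which 3 still matched none with current symbols. The cytosolic ribosomal, mitochondrial ribosomal, proteasome and cuticle lists were taken by a pattern of the symbol. They may therefore hold genes of another function. A further test drew 10000 gene sets matched on the number of TSSs. These tests treat genes as independent, although neighbouring genes can share a region. For motifs and 8-mers, a window of 50 bp either side of the summit was compared with a window of the same size centred 300 bp away on a randomly drawn side of the same peak, by the exact McNemar test with Benjamini-Hochberg adjustment. The 10 8-mers with the largest excess on arms 2L, 2R and 3L were tested on 3R and X. Base composition was measured within 25 bp of the summit. Values given as log2 odds ratios or log2 ratios had 0.5 added to each count. They therefore differ from the log2 of the odds ratios printed without it, most of all where counts are small. Discordant peaks are those with a motif or word in only 1 of the compared windows. A threshold of 0.05 was used throughout, on the adjusted p where one is given. Elsewhere, as for the X share and the promoter signal, it was applied to the single p without adjustment.

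Named genes follow a rule fixed before the data were examined. It takes CG7368, the gene with the nearest TSS for each of the 25 highest optimal peaks, the 5 protein-coding genes with the most optimal summits in the gene or 1 kb upstream, and up to 3 members per list with the highest promoter signal. The rule also takes the 5 leading 8-mers and each motif past the threshold. Main tests and 34 alternatives were fixed at the same time. Those alternatives cover the overlap rule, the promoter window, a stricter list, other backgrounds, other windows and word lengths, dm3 lists and leaving out each replicate. Except for replicate agreement, leaving out a replicate kept the optimal peaks that overlapped the 5246 highest regions of both other replicates. Optimal peaks, pooled signals, eligible genes and regions not retained still drew on all 3 replicates, so this is a filter on agreement. Base composition, the shuffled-sequence control, the next regions by signal as background, transposable elements as TSSs, current gene symbols and several replicate checks were chosen after seeing the data.

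The statistical functions were tested on simulated data. For the promoter comparison on 5246 peaks, a simulated odds ratio of 2.31 was recovered as 2.43. For the 8-mer comparison, a word planted at 8.76 percentage points above the flank on 2238 test peaks came back first at 8.67 points. For the gene lists, run on 5039 genes, 98 of 100 lists of 60 genes bound at 50% against 25% were called, and 1 of 100 lists with no difference was. These calls used Fisher's exact test at 0.05 without adjustment. Apart from the ribosomal list with 75, the lists tested had 2 to 27 eligible genes. The simulation therefore does not tell how often a difference in such small lists would be missed. For the permutation of median signal, run on sets of 2000 simulated values, 6 of 100 sets with no difference and 82 of 100 with a 1.1-fold difference were called. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.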

Results

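Binding of the CG7368 protein, which carried a green fluorescent protein tag, was mapped in whole prepupae of mixed sex, the stage at which larval tissues begin to be replaced. The series holds 1 group of 3 biological replicates, so the comparisons are between replicates, between classes of genomic region and between groups of genes. Each replicate list and the pooled list held 30000 regions in dm6 coordinates, and the optimal list held 5246 peaks with a median width of 416 bp. Optimal peaks can overlap, and 6 repeated the interval of another, so counts of peaks are not counts of separate sites. All 5246 optimal peaks were in the pooled list and were the 5246 regions of highest signal there, with signals from 104.1 to 3148. Comparisons of optimal peaks with regions not retained are therefore comparisons of high with lower signal. Signals are the authors' values, and the median signal of the full lists was 14.6 in replicate 1, 18.4 in replicate 2 and 18.5 in replicate 3.

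The first question was whether the replicates marked the same places. Of the 5246 highest regions, 76.0% were shared by replicates 1 and 2, 74.7% by replicates 1 and 3, and 78.7% by replicates 2 and 3, against a mean of 2.86% and a maximum of 3.66% after shuffling. Among optimal peaks, 5150 (98.2%) overlapped a region in the full list of every replicate. Optimal peaks were drawn from the alignments of these same replicates, so this overlap is partly built in. It was not set against shuffled positions. Fewer, 3465 (66.1%), overlapped the 5246 highest regions in all 3 replicates, 1202 did so in 2, 539 in 1 and 40 in none. Across shared regions, which are not independent replicates, Spearman's rho of signal ranged from 0.749 to 0.795. Requiring a 50% reciprocal overlap lowered the mean of the 3 pairs from 76.5% to 68.0%.

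CG7368 (FBgn0036179), the gene whose product was tagged, lies on the plus strand of 3L at 11597202 to 11605374 and carried 5 optimal peaks within 1 kb of its body. The strongest, at 11602045 to 11602460, had its summit in an intron 822 bp from the nearest TSS, a signal of 246 and rank 1478 of the optimal list. Regions at this intronic place had rank 1393 in replicate 1, 2027 in replicate 2 and 1164 in replicate 3. A second intronic peak at 11599184 to 11599599 had a signal of 204, and 3 further peaks had promoter summits with signals of 156, 121 and 167. The peak of signal 121, at 11599386 to 11599801, overlaps this second intronic peak.

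**Figure D1:**
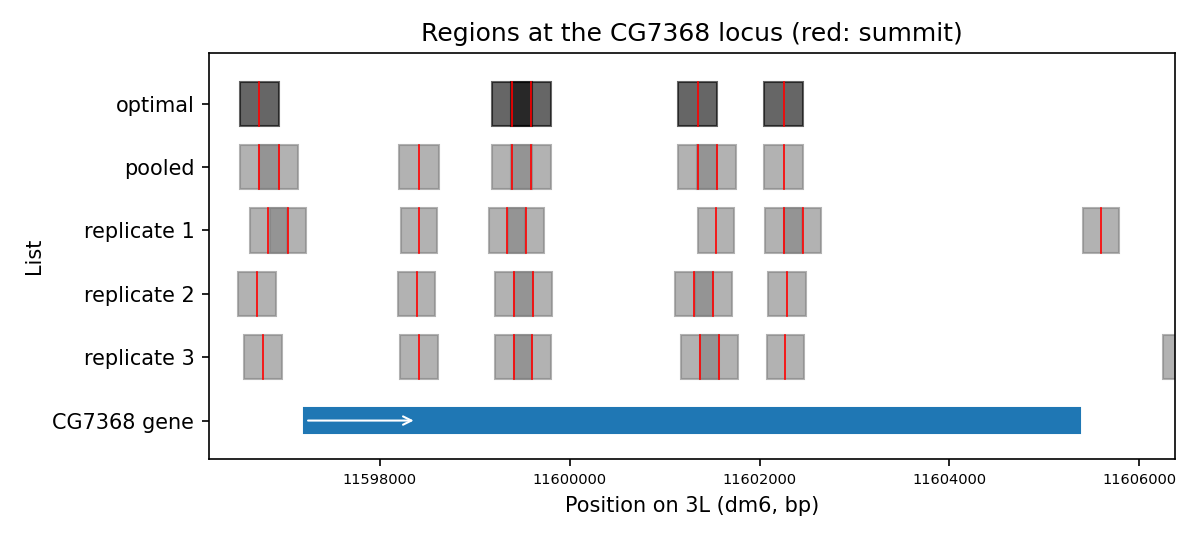
Regions of 5 lists drawn to scale along 3L (dm6, bp) around CG7368, with summits in red and the gene with its direction of transcription in blue. Replicates 1, 2 and 3 each have a region at the strongest optimal peak, whose summit is at 11602253.

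The very highest peaks had the same order in every replicate. The first 3 ranks of the optimal list, at Ugalt, CG14100 and cbt, were also ranks 1, 2 and 3 in each of the 3 replicates. Ugalt (FBgn0024994), which encodes a UDP-galactose transporter, had the highest peak, at X 2703691 to 2704086, with a signal of 3148 and a summit 33 bp from the TSS. The peak nearest CG14100 (FBgn0036889), at 3L 19590435 to 19590807, had a signal of 2264 and a promoter summit. The peak nearest cbt (FBgn0043364), which encodes the zinc finger protein Cabut, lay at 2L 480881 to 481283 in an intron of the neighbouring gene ush, with a signal of 2119. CG11050 had an intronic peak of signal 1932, and CenG1A, an Arf GTPase-activating protein gene, had a promoter peak of signal 1843 that also lay at the TSS of mRpS23.

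Of the 25 highest peaks, 13 had promoter summits, 8 intronic, 3 intergenic and 1 in a noncoding exon, and all 25 ranked within the first 100 in each replicate, with 44 the lowest rank. Promoter peaks included larp, an RNA-binding protein gene (signal 1825), PNPase (1658), CG1888 (1653), Chro, which encodes the chromosomal protein Chromator (1597), and mRpL41 (1475). CG13921 (1472), lncRNA:CR31044 (1430), the small heat shock gene Hsp27 (1397), the arginine methyltransferase gene Art3 (1328) and the translocation protein gene Trp1 (1322) completed the promoter group. Introns held the peaks nearest the kinase gene Lk6 (1728), CG32772 (1638), CG11362 (1425), CG16753 (1390), CG9663 (1369) and CG3726 (1302). Intergenic summits were nearest CG13323 (1542), CG43245 (1361) and CG31668 (1349), and the noncoding exon summit was at lncRNA:CR46035 within osa (1524). Below the first ranks the order varied, with CG9663 at ranks 44, 14 and 27 in replicates 1, 2 and 3, Art3 at 23, 13 and 42 and CG11362 at 5, 33 and 22.

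Genes with many peaks were long. The gene kirre, which encodes an adhesion protein of myoblast fusion, held 22 optimal summits over 394 kb on X (2740384 to 3134532). CG1677 held 19 over 125 kb, the supervillin gene Svil 18 over 122 kb and the nuclear repressor gene sbb 18 over 79.1 kb. CG43658 held 16 over 105 kb, as did shn over 58.3 kb, which shared that count and is outside the naming rule. At least 1 optimal summit lay in or within 1 kb upstream of 3000 protein-coding genes, and 177 genes had 5 or more.

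Promoters were more common among optimal peaks. Summits lay within 500 bp of a TSS in 2010 of 5246 optimal peaks (38.3%, Wilson interval 37.0 to 39.6) and in 4858 of 23643 regions not retained (20.5%). The odds ratio was 2.40 (95% interval 2.25 to 2.56, Fisher's exact test, p = 9.28e-152). In the 5246 highest regions of single replicates the share was 39.8% ± 0.921 (SD, n = 3), against 21.8% ± 1.98 (SD, n = 3) in their other regions. Introns held 42.9% of optimal peaks and 47.4% of regions not retained, and intergenic DNA held 16.2% and 26.3%. Coding exons held 0.267% of optimal peaks against 2.14% (odds ratio 0.122, adjusted p = 8.44e-28, Fisher's exact test), and 3′ UTRs held 0.553% against 1.54%. Noncoding exons, with 1.18% and 1.15%, did not differ past the threshold (Fisher's exact test, p = 0.83).

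Promoter share fell along the ranking of the pooled list, from 40.6% of the first 3000 regions to 14.1% of the last 3000. Against the next 5246 regions by signal, chosen as background after seeing the data, 38.3% stood against 31.1% and the odds ratio was 1.38.

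**Figure D2:**
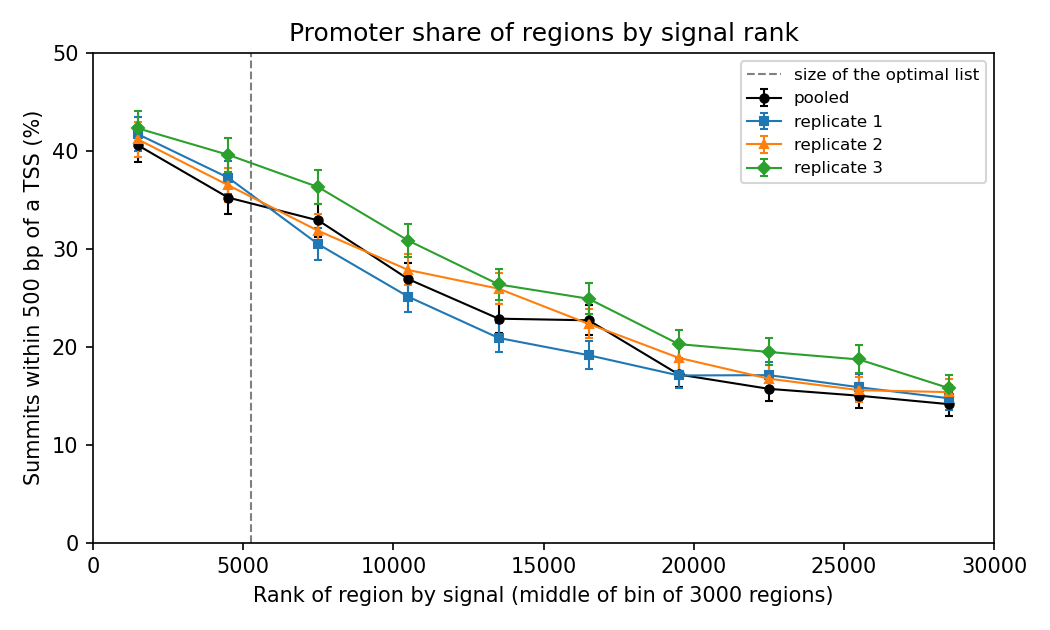
Share of summits within 500 bp of a TSS (%) in bins of 3000 regions ordered by signal rank, for the pooled list and each replicate, with 95% Wilson intervals as bars and the size of the optimal list as a dashed line. The pooled share falls from 40.6% in the first bin to 14.1% in the last.

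At optimal peaks, promoter summits also had a somewhat higher signal, with a median of 177 against 164 elsewhere. The difference of 13.3 (bootstrap interval 7.62 to 20.1) gave p = 3e-05 by permutation. Signals of the same peaks in single replicates differed by 3.62, 5.91 and 7.61, so promoter medians were 1.09, 1.09 and 1.12 times those of other peaks. Among optimal peaks that were also in the highest regions of both replicates kept, a choice made after seeing the data, the difference in optimal signal was 25.7 without replicate 1, 23.4 without replicate 2 and 26.01 without replicate 3. All 3 replicates had the same direction, for which 3 values alone cannot give a p below 0.25.

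Peaks were spread over the chromosome arms at similar densities. The X had 42.4 optimal peaks per Mb, 3L 42.2, 2L 39.1, 3R 38.6 and 2R 35.4, while chromosome 4, the small and largely heterochromatic chromosome, had 6.68 per Mb from 9 peaks. None of the 5246 optimal peaks was on Y. X held 19.1% of optimal peaks on the 5 arms and 17.9% of regions not retained (odds ratio 1.08, 95% interval 1.00 to 1.17, Fisher's exact test, p = 0.0497). Shares on X were 19.6%, 20.7% and 17.6% in the highest regions of replicates 1, 2 and 3 (19.3% ± 1.58, SD, n = 3). Within each replicate X held more of the highest regions than of the other regions, with odds ratios of 1.16, 1.08 and 1.09 in replicates 1, 2 and 3 (Fisher's exact test, p = 1.05e-04, 0.0479 and 0.0421), a comparison chosen after seeing the data. In the dm3 lists Fisher's exact test gave an odds ratio of 1.07 with p = 0.0995.

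Of the 18 gene lists, only the cytosolic ribosomal protein genes had an optimal promoter peak more often than other genes past the threshold. The small muscle structure list (5 of 6, 83.3%) and insulator list (9 of 11, 81.8%) had shares as high without passing. Of 5039 protein-coding genes with any pooled region at a promoter, 2079 (41.3%) had an optimal promoter peak, which is 14.9% of all protein-coding genes. Cytosolic ribosomal protein genes, taken by symbol and mostly encoding components of the translating ribosome, had one in 60 of 75 eligible members (80%) against 40.7% of other genes (odds ratio 5.83, 95% interval 3.30 to 10.3, adjusted p = 1.22e-10, Fisher's exact test). The 60 included RpLP0-like, whose summit was nearer to the TSS of 14-3-3zeta. The odds ratio was 4.70, 6.15 and 4.82 with the highest regions of replicates 1, 2 and 3. RpS27 had a signal of 601 at 3R 25247391 to 25247653, 6 bp from a TSS, RpL7 a signal of 486 at 2L 10200931 to 10201159 and RpL32 a signal of 466 at 3R 30046121 to 30046458, where the TSS of CG7943 was nearer to the summit. Over all lists, 27 of 153 members with an optimal promoter peak had a summit nearer to the TSS of another gene.

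Cuticle protein genes, which encode structural proteins of the exoskeleton, were the opposite case. Only 1 of 26 eligible members, Cpr73D (signal 128, 3L 16957752 to 16958167), had an optimal promoter peak (3.85% against 41.5%, odds ratio 0.0565, adjusted p = 2.24e-04, Fisher's exact test). Its rank was 3248, 10488 and 2521 in replicates 1, 2 and 3. Of the 116 annotated genes that the symbol pattern took, 26 were eligible. Log2 odds ratios, with 0.5 added to each count, were -4.68, -2.92 and -4.58 without replicates 1, 2 and 3, against -3.59 with all. With so few members bound, their size depends on that addition. With sets matched on TSS number, both lists gave an adjusted p of 0.0018. Members of a list that are neighbours in the genome are not independent, which neither test takes into account.

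No other list passed the threshold. Ecdysone response genes, which act downstream of the moulting hormone, had 16 of 25 bound (64%, Fisher's exact test, adjusted p = 0.089), led by the nuclear receptor gene Eip75B (signal 461), Ldh (390) and Eip93F (273). Its log2 odds ratio was 1.31, against 0.50, 0.85 and 0.60 without replicates 1, 2 and 3, and 0.33 among the 50% of peaks with the highest signal. It passed with a promoter window of 1000 bp (adjusted p = 0.0246) and against all protein-coding genes (1.23e-06), and its adjusted p in the other alternatives ranged from 0.152 to 0.893 by Fisher's exact test or matched permutation. Insulator and architectural protein genes had 9 of 11 (Fisher's exact test, adjusted p = 0.0621), led by Chro (1597), Cp190 (613) and Trl, the GAGA factor gene (440), with the TSS of CG4338 nearer to the Cp190 summit. Their log2 odds ratio was 2.44, against 1.31, 1.43 and 1.41 without replicates 1, 2 and 3, and 1.07 for regions in the top of all 3. They passed with the 1000 bp window (adjusted p = 0.0449) and against all protein-coding genes (6.64e-04), and adjusted p elsewhere ranged from 0.0621 to 0.706 by Fisher's exact test or matched permutation. None of 8 eligible Hox genes, the regulators of segment identity, was bound (Fisher's exact test, adjusted p = 0.089). This list passed with the 1000 bp window (Fisher's exact test, adjusted p = 0.0449), and its adjusted p elsewhere ranged from 0.0924 to 0.691 by Fisher's exact test or matched permutation.

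Mitochondrial ribosomal protein genes had 13 of 27 bound (48.1%), led by mRpS23 (1843), mRpL41 (1475) and mRpS10 (1328). The mRpS23 and mRpS10 summits were nearer to the TSSs of CenG1A and Art3, and the TSS of lncRNA:CR44463 was also within 500 bp of the mRpL41 summit. Summits at mRpS2, mRpL24, mRpL18, mRpL20, mRpL2, mRpL34, mRpS26 and mRpS7 were likewise nearer to the TSS of another gene, so most of these peaks cannot be assigned to the mitochondrial gene. Cell death and autophagy genes had 9 of 17, led by the apoptosis activator hid (484), Atg17 (404) and Atg2 (371), with the TSSs of Xe7 and CG12093 nearer to the latter summits. Notch pathway genes had 9 of 15, led by aph-1 (317, nearer to the TSS of Snx21), E(spl)m7-HLH (269) and E(spl)m3-HLH (246). Hippo pathway genes had 6 of 10, led by Mer (473), app (367) and ft (310). Imaginal disc patterning genes had 11 of 26, led by bi (166), mirr (150) and so (148). Adjusted p for these 5 lists ranged from 0.377 to 1 by Fisher's exact test. Against all protein-coding genes, which include genes without any pooled region at a promoter, the cell death (0.0298), Notch (0.0197) and Hippo (0.0361) lists passed by the same exact test. Among the 50% of optimal peaks with the highest signal, the imaginal disc list was lower than other genes (Fisher's exact test, adjusted p = 0.00577), the direction opposite to the full list, while against all protein-coding genes it was higher (0.0314). Adjusted p in its other alternatives ranged from 0.0935 to 1 by Fisher's exact test or matched permutation.

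Tissue lists were small. Muscle structure genes had 5 of 6 bound, led by Msp300 (510), Mef2 (155) and Tm1 (130), and their log2 odds ratio of 2.39 became 1.65 with current symbols, added after seeing the data. Neuronal genes had 3 of 15, namely elav (612), futsch (168) and Sh (148). Glial genes had 3 of 6, namely moody (612), loco (168) and wrapper (120). Fat body genes had 3 of 5, namely bmm (219), Apoltp (212) and FASN1 (116), and hemocyte genes had 1 of 3, crq (158). Proteasome genes had 4 of 10, led by Rpn3 (277), Rpn5 (257, nearer to the TSS of Hat1) and Rpn13 (106). Ecdysone synthesis genes had 0 of 4, and salivary glue and late puff genes had 0 of 2. Adjusted p for these 8 lists ranged from 0.264 to 1 by Fisher's exact test.

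**Figure D3:**
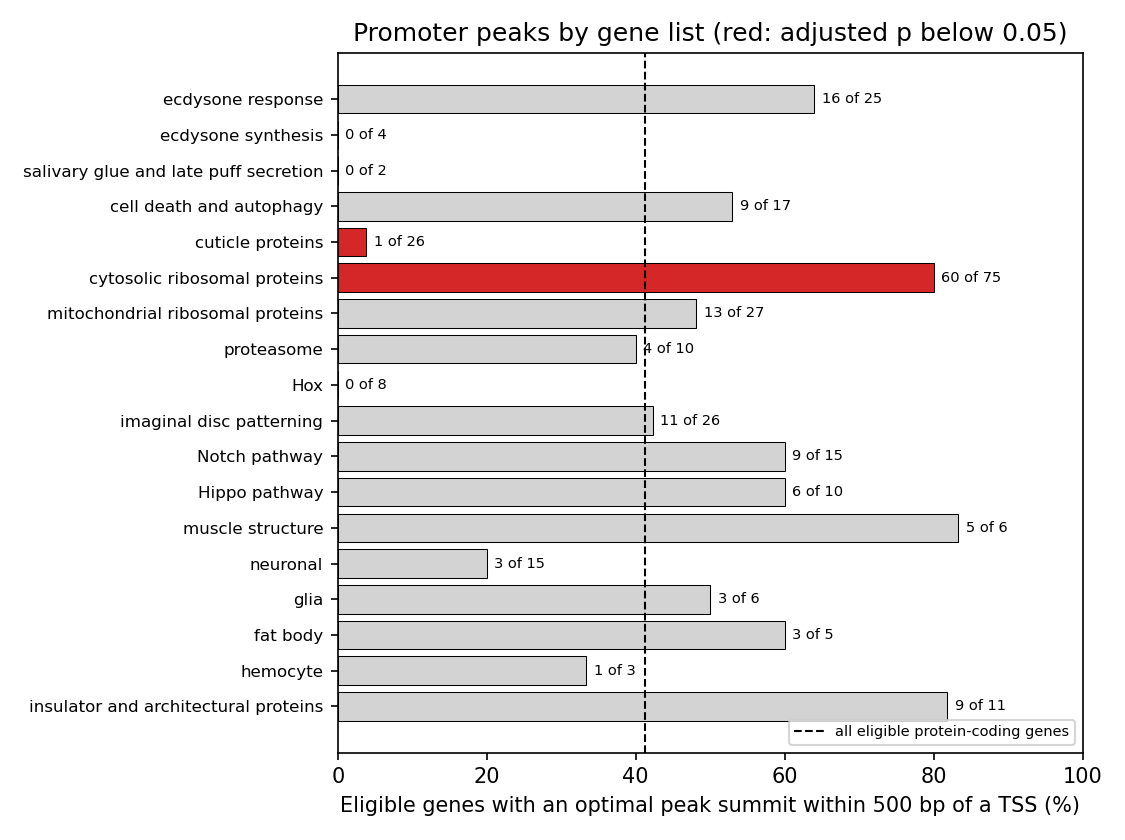
Share of eligible genes (%) with an optimal peak summit within 500 bp of a TSS for 18 gene lists, with bars in red past an adjusted p of 0.05 and a dashed line at 41.3% for all eligible protein-coding genes. Cytosolic ribosomal proteins reach 80% and cuticle proteins 3.85%.

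Summits were rich in A and T. Within 25 bp of the summit, 65.2% of bases were A or T, against 55.1% in the flank (difference 10.1 percentage points, SE 0.236, over 5246 peaks), a measure chosen after seeing the data. In the highest regions of single replicates the difference was 9.02 ± 0.988 points (SD, n = 3). It was 7.20 points at promoter peaks and 11.9 at other peaks, and it was 0.891 in regions not retained. The size of the difference depends on the flank, which lay in a local dip of A and T. At optimal peaks the share was 55.2% and 55.3% at offsets of -300 and 300 bp. It was 57.8% and 57.9% at -1000 and 1000 bp, still below the summit. Regions not retained had 57.97% at the summit, against 58.24% and 58.02% at -1000 and 1000 bp. Flanks for motifs and words were centred at the same 300 bp.

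Of 19 known motifs, 11 differed between summit and flank, 5 higher at the summit and 6 lower. The TATA box motif TATAAA was in 19.9% of summit windows and 9.70% of flanks (adjusted p = 8.15e-48, exact McNemar test), and in single replicates in 18.8% ± 0.816 against 9.27% ± 0.183 (SD, n = 3). AAAAAAA (14.2% against 10.3%), the homeodomain motif TAATTA (8.39% against 5.36%), the GATA factor motif WGATAAG (3.72% against 2.73%) and the DREF and BEAF-32 motif TATCGATA (0.762% against 0.305%) were also more frequent at summits. The CA repeat CACACAC (2.86% against 6.14%), the GAF and CLAMP motif GAGAGAG (2.15% against 3.18%) and the E-box CAGCTG (3.62% against 5.05%) were less frequent. So were CAGGTAG of Zelda (0.248% against 0.667%), RGGAATG of Scalloped (1.49% against 2.17%) and AGGKGGC of CTCF (1.58% against 2.34%).

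Several of these directions changed with the control. Against shuffled summit sequences with the same dinucleotides, chosen as control after seeing the data, GAGAGAG was higher at real summits (2.15% against 0.667%), as were CACACAC (2.86% against 1.24%), CAGCTG (3.62% against 1.66%), AGGKGGC and TATCGATA (0.762% against 0.133%). TAATTA was lower (8.39% against 10.4%), AAAAAAA did not differ past the threshold (exact McNemar test, adjusted p = 0.549), and TATAAA remained higher at 19.9% against 17.9% (adjusted p = 0.0111). CAGGTAG (0.238), WGATAAG (0.0597) and RGGAATG (0.447) also no longer passed by this exact test. Unshuffled regions not retained also held GAGAGAG (2.60%), CACACAC (5.52%), CAGCTG (4.51%), AGGKGGC (2.55%) and TATCGATA (0.419%) more often than shuffled summit sequences. Flanks and regions not retained were not shuffled, so this control cannot tell whether an excess over shuffled sequence is particular to summits.

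Other settings ended the call of 5 motifs, here with log2 ratios of discordant peaks and adjusted p by the exact McNemar test unless named otherwise. GAGAGAG, at -0.59 in the full set, had -0.19 with a 100 bp window (0.162) and a log2 odds ratio of -0.27 against regions not retained (Fisher's exact test, 0.111). CAGGTAG, at -1.39, had -0.43 with the 100 bp window (0.184). The remaining losses came with fewer peaks. TATCGATA, at 1.295, had 1.14 away from promoters (0.538), 0.61 among the 50% highest peaks (0.504), 0.97 without replicate 2 (0.092) and 1.08 without replicate 3 (0.0531). CAGGTAG had -1.51 among the 50% highest peaks (0.0538) and -1.38 away from promoters (0.05002). RGGAATG, at -0.56, had -0.68 among the 50% highest peaks (0.0946) and -0.56 without replicate 3 (0.0525), and AGGKGGC, at -0.57, had -0.54 among the 50% highest peaks (0.127).

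Calls were also gained by motifs that did not pass in the full set, which are named here after their values were seen. The M1BP motif GGTCACACT, at 1.12 in the full set (exact McNemar test, adjusted p = 0.11), passed with the 100 bp window (1.14, 0.0123), away from promoters (3.91, 0.0297) and against shuffled sequence (5.21, 2.90e-05). By the same exact test, TCAAGGTCA of FTZ-F1 passed with the 100 bp window (-1.95, 0.0367), ACYNGTT of Grainyhead without replicate 3 (-0.29, 0.046) and the initiator TCAGTY against shuffled sequence (0.24, 0.0386). The first 2 motifs were rare. In the full set GGTCACACT was in 18 summit windows, 8 flank windows and 0% of shuffled sequences, and TCAAGGTCA in 1 summit window and 4 flank windows. The sizes of 3.91 and 5.21 depend on the 0.5 added to each count.

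**Figure D4:**
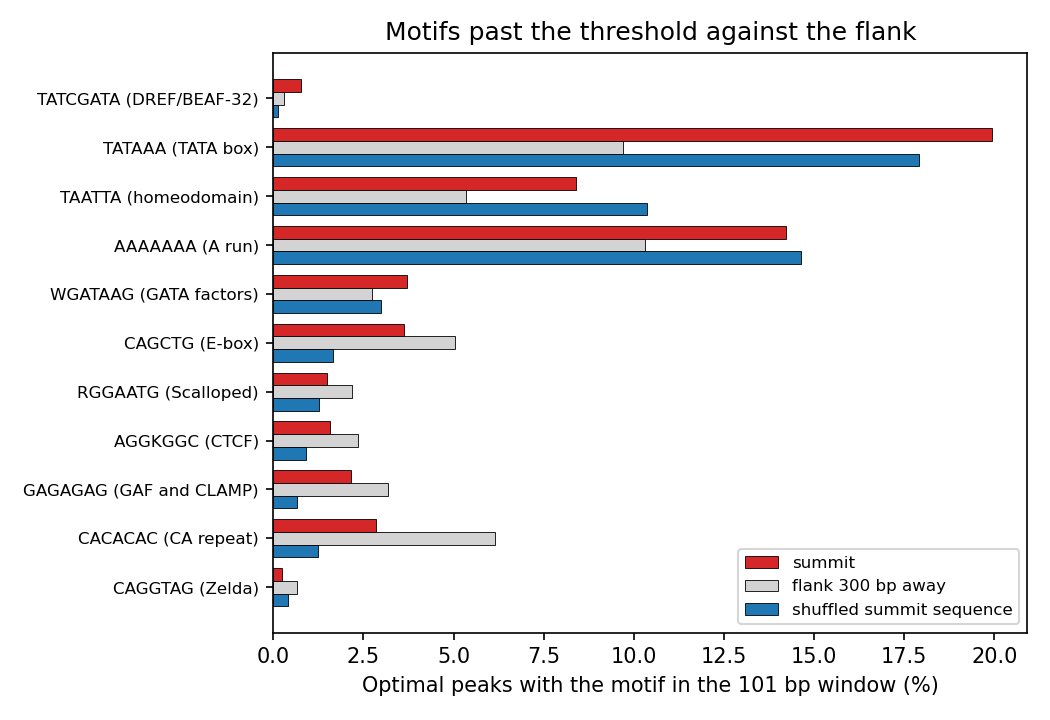
Share of 5246 optimal peaks (%) with each of the 11 motifs past the threshold, within 50 bp of the summit, in the flank 300 bp away and in shuffled summit sequence. TATAAA is at 19.9%, 9.70% and 17.9%, and GAGAGAG at 2.15%, 3.18% and 0.667%.

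All 10 8-mers carried over from 2L, 2R and 3L consisted of A and T only, and 9 were more frequent at summits than flanks on 3R and X (2238 peaks). ATTTAAAA was in 4.87% of summit windows against 2.14% (adjusted p = 2.23e-06, exact McNemar test), TTTAAAAA in 4.38% against 2.01%, AAAATATT in 5.45% against 2.23% and TATTTAAA in 3.93% against 1.52%. AAAAAAAA, in 10.01% against 8.71%, did not pass (exact McNemar test, adjusted p = 0.145). Against shuffled sequence, with adjustment over these 5 words, AAAATATT (exact McNemar test, adjusted p = 0.0201) and AAAAAAAA (3.33e-06) were higher and TTTAAAAA was lower (log2 ratio -0.48, adjusted p = 0.0317). ATTTAAAA (0.678) and TATTTAAA (0.361) did not differ past the threshold by this exact test. With the 100 bp window AAAAAAAA also passed (exact McNemar test, adjusted p = 0.00245).

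**Figure D5:**
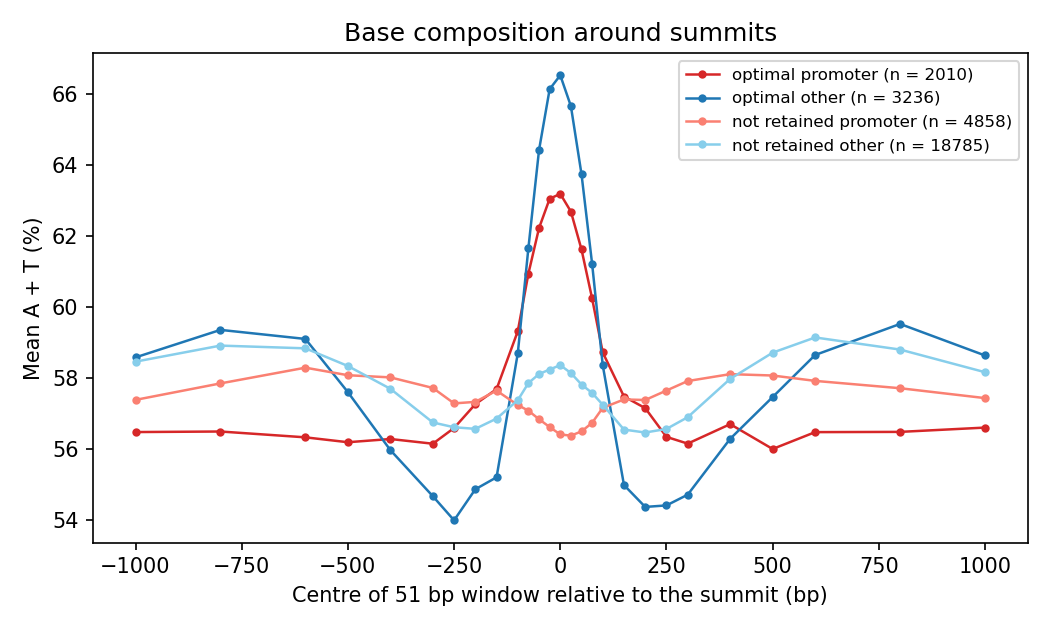
Mean share of A and T (%) in windows of 51 bp placed at offsets from the summit (bp), for promoter and other summits among optimal peaks and regions not retained. At the summit, optimal promoter peaks reach 63.2% and other optimal peaks 66.5%, against 56.4% and 58.4% in regions not retained.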

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

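Tests of AT-rich summits and of the sex ratio were chosen only after the result was seen, the test matched on TSS number was fixed before the data were examined although what it would exclude was written after its result, and that of high expression was written before.

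The dm3 lists held regions on scaffolds outside the chromosome arms, and the dm6 lists held none. There were 27 of 30000 in the pooled dm3 list, the highest at rank 6140, which no comparison above used, and 100, 32 and 16 in replicates 1, 2 and 3, where the highest had ranks of 4987, 5536 and 2924. Of the 5029 highest regions per replicate, which replicate agreement in dm3 used, 1 was on such a scaffold in replicate 1, 0 in replicate 2 and 2 in replicate 3. The optimal dm3 list held 0 of 5029.

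The X chromosome share of the highest regions was 3.11 percentage points higher in replicate 2 than in replicate 3 (95% interval 1.61 to 4.62, which treats regions as independent). A different share of males among the pooled animals may account for it. It was tested on 3998 optimal peaks in the highest regions of both replicates, ranked among themselves by signal within each. Peaks on X ranked higher in replicate 2 than in replicate 3 by a median of 2.60 percentage points of that ranking more than autosomal peaks (bootstrap interval 1.53 to 3.83), while each of the 4 autosomal arms was offset by at most 0.225. Sex was not recorded per replicate, so other causes that act on the whole X stay open.

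The high AT content of optimal summits was weighed against technical causes, with each excess taken over the flank 300 bp away. Summit placement that favours A and T alike in any region is argued against by the excess of 0.891 percentage points in regions not retained. Those regions have lower signal, so this test cannot decide on a placement effect that grows with signal. Among optimal peaks the excess rose from 7.59 points in the lowest of 5 signal classes to 13.0 in the highest. Promoter composition is argued against by the 11.9 points at peaks away from promoters. Whether AT-rich summits are a property of open regulatory DNA that another factor's peaks would share cannot be told apart from a preference of this protein. The next 5246 regions by signal had an excess of 4.13 points (95% interval 3.64 to 4.62), between optimal peaks and all regions not retained. No peaks of another factor were analysed. With a single group in the design, no biological explanation of the AT content was tested by a comparison of groups.

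The high share of ribosomal protein gene promoters is not accounted for by the number of TSSs, since sets matched on it gave a permutation p = 0.0002, the smallest they can give. High expression was tested with a list of 35 other highly expressed genes fixed beforehand from general knowledge. Of 28 eligible, 15 had an optimal promoter peak (53.6%, Wilson interval 35.8 to 70.5), below the 80% of ribosomal protein genes (Fisher's exact test, p = 0.012). Expression in these animals was not measured, so a preference of this protein for these promoters remains a hypothesis, and nonspecific precipitation at these genes, for which no control precipitation was analysed, stays open.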

How the results depend on the processing

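Tests against shuffled sequence, the next regions by signal, transposable elements, current symbols, single replicates for X, and without each replicate for 8-mers and signal were chosen only after the result was seen. The promoter share, promoter signal and the calls of ribosomal and cuticle genes kept their direction and their side of the threshold under all alternatives run, although the difference in promoter signal was 13.3 with all replicates and between 23.4 and 26.01 without each replicate, where fewer peaks were kept. Promoter odds ratios ranged from 1.38 to 3.99. No paired analysis was possible because the series has only 1 group. Replicate agreement moved to 68.0% with a 50% reciprocal overlap, 69.4% with summits within 100 bp and 81.8% for the 1000 highest regions, and ranged from 74.7% to 78.7% without each replicate. The X odds ratio was 1.07 in the dm3 lists, no longer past the threshold, and 1.11 to 1.17 without each replicate. Instead of 2 lists, 5 passed with the 1000 bp window and 8 with all protein-coding genes as background. Instead of 11 motifs, 7 passed among the 50% highest peaks, a list with fewer peaks, and instead of 9 8-mers, 5 of another set of 10, selected and tested against shuffled sequence, passed. The cause of the other changes was not tested.

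Values that changed direction are log2 odds ratios for lists and for motifs against regions not retained, and log2 ratios of discordant peaks for other motif and word settings. Against shuffled sequence they were -0.0680 for AAAAAAA, 0.83 for AGGKGGC, 1.41 for CACACAC, 1.19 for CAGCTG, 2.02 for GAGAGAG, 0.25 for RGGAATG, -0.37 for TAATTA, -0.51 for TGASTCA, 0.42 for TGTTTAC, -0.10 for ATTTAAAA and -0.48 for TTTAAAAA. Away from promoters they were -0.39 for TGASTCA and 0.0937 for TGTTTAC, against regions not retained 0.0509 for ACYNGTT and 0.0538 for TGTTTAC, and with the 100 bp window -0.0108 for TCAGTY and 0.0844 for TGTTTAC. Among lists, the 50% highest peaks gave -0.24 for glia, -0.24 for muscle structure and -4.11 for imaginal disc patterning. The size of -4.11 depends on the 0.5 added to each count. Regions in the top of all 3 replicates gave 0.57 for hemocyte and -1.99 for imaginal disc patterning, which was -0.0815 with the 1000 bp window. With the 250 bp window, values were -0.27 for Notch pathway, -0.96 for glia and -0.60 for muscle structure. Neuronal genes had 0.12 against all protein-coding genes, and proteasome genes 0.0496 when matched on TSS number. Without each replicate, imaginal disc patterning ranged from -1.69 to -0.81 and hemocyte from 0.32 to 0.44, cell death and autophagy from -0.00365 to 0.90, and proteasome from -0.71 to 0.63. Among single lists, motifs and words, 312 values kept direction, of which 17 passed the threshold only under the alternative and 15 only in the main test. Of the 36 that changed direction, 1 passed only under the alternative and 3 only in the main test.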

Other observations

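These tests were all chosen after seeing the data. Promoter summits of optimal peaks lay mostly upstream of the nearest TSS of a protein-coding gene. Of 1851 such summits, 1431 (77.3%, Wilson interval 75.3 to 79.2) were upstream, with a median position of -116 bp, and 49.0% lay in the 200 bp before the TSS. Regions not retained had 60.7% upstream and a median of -45 bp (odds ratio 2.21, Fisher's exact test, p = 2.11e-37). In single replicates the upstream share was 76.6% ± 1.22 (SD, n = 3).

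Transfer RNA genes were bound less often than protein-coding genes. Of 112 tRNA genes with a pooled region at the promoter, 16 (14.3%) had an optimal peak, against 41.3% of protein-coding genes (odds ratio 0.237, adjusted p = 2.97e-09, Fisher's exact test). Noncoding RNA genes of the annotation had 246 of 951 (25.9%, Fisher's exact test, adjusted p = 3.85e-19). Small nucleolar RNA genes had 11 of 36, small nuclear RNA genes 1 of 9 and pseudogenes 9 of 20, none past the threshold. A gene counted as bound with an optimal summit at any of its TSSs, and gene types were not matched on the number of TSSs. Neighbouring genes can share a peak, so these counts are not independent.

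The sequence CAGTG was, on either strand, part of 3 of the 10 leading 6-mers against shuffled summit sequence. On the test arms all 3 were more frequent at real summits than in shuffled sequence. The shares were 7.51% against 3.35% for ACAGTG (exact McNemar test, adjusted p = 2.82e-09), 6.84% against 3.49% for CAGTGC (7.44e-07) and 6.08% against 3.89% for CACTGA (0.00134). Flanks were not shuffled here either. Between signal classes CAGTG itself did not differ past the threshold, with 22.5% of optimal summit windows and 22.1% of regions not retained (Fisher's exact test, p = 0.607).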
